A study of Mus musculus with 16 samples.

How the data were processed

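RNA was sequenced from mouse CD8+ T cells of C57BL/6 background, activated for 2 days with antibodies to CD3 and CD28 and then kept for 36 h in 1 of 4 media. The media were fresh medium without methionine, fresh medium with methionine (complete fresh medium), supernatant of B16F10 cells, a mouse melanoma line, and the same supernatant with methionine added (supplemented supernatant). Each medium had 4 libraries, 16 in all, and every column of the deposited tables was matched to its library by name. The labels do not say whether the 4 libraries of a group came from separate animals or separate cultures, so every p-value below measures the spread between libraries. The replicate numbers of the groups are not stated to pair libraries. In 24 pairs of libraries with the same number in different groups, the correlation of the residuals lay between -0.07 and 0.07, and 5 of the 16 libraries resembled their own number most, so no pairing was used. In the FPKM table, over 10683 genes, the same correlation was 0.60 to 0.92, against -0.15 to 0.22 for the depth-normalized values of these genes, so counts of genes called from FPKM, and named genes that lost a call there, are also given with a block for the replicate number; list tests from FPKM were run without it.

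Per the submitters' processing notes, the tools were FastQC 0.11.3, TopHat2 2.0.13, Bowtie2 2.2.1, Cufflinks and Cuffdiff 2.2.1, with the builds mm10 and GRCm38. The notes give no role or order for them, and neither the counting tool nor the gene annotation nor the strand used in counting is stated. The first deposited table holds 1 signal per gene and library, which its name calls a depth-normalized count, for 17159 genes. From the values, every signal that the authors deposited is a whole number of reads divided by 1 factor per library, to within 0.001 of a read in 100% of the values, and the factors equal median-of-ratios size factors computed from the recovered reads. The second deposited table holds FPKM (fragments scaled to transcript length and to the number of mapped fragments) per library for 23107 genes, of which 4736 are 0 in every library. The tables share 17136 symbols, and 23 symbols of the first had been turned into dates and were left as they stood. Cytosolic and mitochondrial ribosomal protein genes and genes encoded on the mitochondrial chromosome have no values in the first table and were not analysed here.

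Recovered reads per library ran from 25.8 M to 42.3 M. Over genes with at least 20 reads, the mean chi-square per gene between 24 pairs of libraries of the same group was 2.62 to 9.27, above the value of 1 that counting error alone would give. Because the read strand is not stated, a gene's value may hold reads of overlapping or antisense transcripts, and families of close paralogs (granzymes, Klra receptors, Bcl2a1 genes) may share reads.

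Values were analysed as log2(depth-normalized value + 1), which understates folds of genes near 0 reads. The 12469 genes (72.7%) with a mean of at least 10 over the 16 libraries were tested, and 4690 were not. One linear model with 4 group means was fitted to all 16 libraries in limma 3.58.1 (R 4.3.3) with a mean-variance trend. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, with no minimum fold. The comparisons were methionine removal in fresh medium, supernatant against complete fresh medium, methionine addition to supernatant, supplemented supernatant against complete fresh medium, supernatant against methionine-free fresh medium, and the difference between the methionine effects of the 2 media (interaction). Fold changes of pairs of comparisons were correlated across genes, which are not independent replicates. Where 2 comparisons share a group, the correlation stands beside 100 simulations in which no gene changed and beside the 6 splits of the shared group into separate pairs of libraries.

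Of 39 gene lists, the 36 with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists within each comparison. Each was tested again with an estimated correlation per list, and with fry. The comparisons, the tests, the lists and the first set of alternatives below were chosen before the data were examined. So was the rule for naming genes. For the first 3 comparisons it takes the 6 highest and 6 lowest fold changes among called genes with a mean of at least 100 and no overlap between groups, without predicted genes, small RNAs and pseudogenes. It adds the 2 called genes of each called list that changed most in the direction of the list. It also adds 12 fixed genes: Slc43a2, Stat5a, Stat5b, Dot1l, Mat2a, Il2ra, Bcl2, Ifng, Tnf, Gzmb, Asns and Ddit3. For the other comparisons it takes the 3 highest and 3 lowest, for the interaction without the condition on overlap. A gene picked by this rule is not reported here and was not replaced by the next in rank. Any other gene is given as chosen after its values were seen.

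Symbols were matched to GENCODE vM21 on GRCm38 for positions, GC content and transcript length, directly for 15410 genes and through older names for 1466 (98.4% together). The limma test was tested on simulated data for methionine removal in fresh medium, with 50 genes changed at each size. It called 41 at 1.25-fold, 43 at 1.5-fold, 48 at 2-fold and 50 at 4-fold, and 15 of 12269 unchanged genes. Most genes were left unchanged there, unlike in the data, and limma was given the library factors used to draw the reads. An error of scaling when most genes change was therefore not simulated. A simulated rise of 1.5-fold in the 21 genes of 1 list was called, and 0 of the 35 other lists were. Each gene was drawn independently, so this cannot show how often lists of co-varying genes are called falsely. In the simulation of single genes, edgeR called 15 and DESeq2 called 12 of the unchanged genes.

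That first set was other pseudocounts, a filter of at least 50 or none, TMM and median-ratio factors, quantile normalization, the FPKM table (log2(FPKM + 0.1), mean of at least 0.5), limma without a trend, with a robust trend or with library weights, fits to the compared groups alone, a block for the replicate number, a 2-fold minimum, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library. Added after the data were seen were scaling to total reads, edgeR on 15 libraries, other scalings for the list tests, the FPKM table with each library's trend on GC content and transcript length removed, the FPKM table with the replicate block, and the share of genes moved back by methionine with no shared library. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.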

Results

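RNA sequencing measured gene expression in activated mouse CD8+ T cells after 36 h in fresh medium without methionine, complete fresh medium, B16F10 melanoma supernatant or supplemented supernatant, with 4 libraries per medium. Recovered reads averaged 34.5 M ± 2.10 (SD, n = 4) in fresh medium without methionine and 35.4 M ± 7.63 (SD, n = 4) in complete fresh medium. They averaged 32.9 M ± 6.10 (SD, n = 4) in supernatant and 38.0 M ± 2.73 (SD, n = 4) in supplemented supernatant, with a range of 25.8 to 42.3 M over the 16 libraries. Levels below are depth-normalized reads, each a mean of 4 libraries with its SD, and fold changes are on the log2 scale of the value plus 1, with adjusted p from limma.

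The libraries without added methionine lay apart from those with it. The first principal component held 80.7% of the variance and separated the 8 libraries of fresh medium without methionine and of supernatant from the other 8. The second held 8.67% and separated supplemented supernatant from complete fresh medium. Replicate 1 of supernatant stood apart from the other libraries on the fourth component (-19.3), which held 1.12%.

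**Figure D1:**
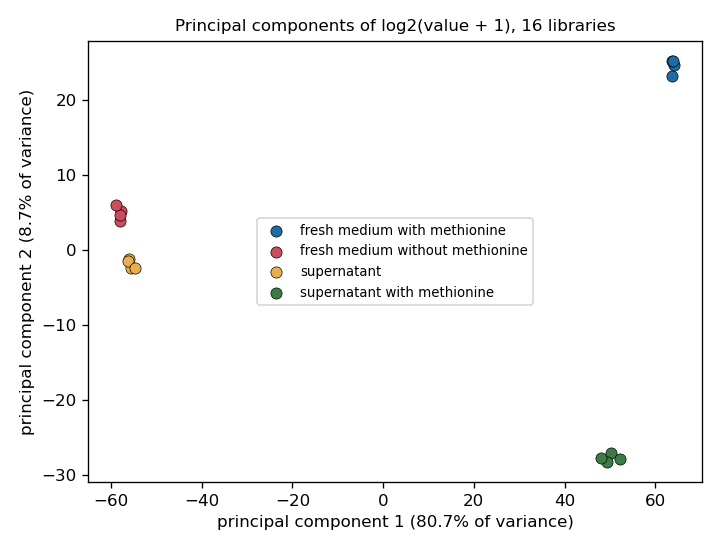
Principal components 1 and 2 of the log2 values of 12469 genes, 1 point per library and 1 colour per medium. Methionine-free fresh medium and supernatant lie together at negative values of component 1, and the 2 media with added methionine lie at positive values and apart from each other on component 2.

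The first comparison asked what removing methionine from fresh medium did to these cells. Without methionine, genes of glycolysis, sterol synthesis and the hypoxia response fell, and the cytokine genes Ifng and Tnf rose. Mat2a, which makes S-adenosylmethionine from methionine, rose from 6636 ± 61.7 to 35416 ± 620 reads (SD, n = 4; log2 fold change 2.42, adjusted p 1.63e-36). Slc43a2, an importer of large neutral amino acids including methionine, fell from 3506 ± 123 to 1025 ± 27.0 reads (SD, n = 4; log2 fold change -1.77, adjusted p 7.03e-29). Ifng, which encodes the cytokine interferon gamma, rose from 71.9 ± 9.15 to 916 ± 50.9 reads (SD, n = 4; log2 fold change 3.66, adjusted p 1.72e-28).

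Transcripts of sterol and sugar metabolism genes fell. Of 25 cholesterol synthesis genes, 24 fell, 0 rose and 1 was not called, both over all genes and adjusted over the list alone, with a median log2 fold change of -2.42. Fdps, an enzyme of isoprenoid synthesis, fell by 4.01 on the log2 scale. The list passed camera (adjusted p 1.03e-11), with adjusted p = 0.0601 with an estimated correlation. All 21 glycolysis genes fell, over all genes and adjusted over the list alone (median -2.17, camera adjusted p 1.13e-10, adjusted p = 0.0335 with an estimated correlation), among them the aldolase gene Aldoc (-5.32) and the lactate transporter gene Slc16a3 (-3.63). All 19 hypoxia response genes fell, again by both adjustments (median -2.08, camera adjusted p 8.47e-09, adjusted p = 0.0335 with an estimated correlation), including Bnip3 (-3.86), a mitophagy receptor, and Adm (-3.94), which encodes a vasodilator peptide and had as few as 0 reads in a library. Of 18 fatty acid synthesis genes, 15 fell and 3 rose by both adjustments (median -1.21, camera adjusted p 1.12e-05, adjusted p = 0.0601 with an estimated correlation). The desaturase genes Fads2 (-4.92) and Scd1 (-3.64) fell most.

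Nuclear genes of oxidative phosphorylation fell by less. Of 44, 43 fell and 1 was not called by either adjustment, with a median of -0.64, and Sdhb (-1.91), a subunit of complex II, and Atp5c1 (-1.79), a subunit of ATP synthase, fell most. This list's call (camera adjusted p 1.09e-09) had adjusted p = 0.477 with an estimated correlation. Of 34 genes of mitosis and S phase, 29 fell, 3 rose and 2 were not called by either adjustment (median -0.58, camera adjusted p 6.27e-07, adjusted p = 0.208 with an estimated correlation), with the spindle checkpoint kinase gene Bub1 (-1.49) and the cyclin gene Ccnb2 (-1.40) as examples. Of 24 NRF2 and glutathione genes, 17 fell, 6 rose and 1 was not called by either adjustment (median -0.43, camera adjusted p 0.0478, adjusted p = 0.553 with an estimated correlation). Nqo1 (-2.27), a quinone reductase, and Tkt (-2.06), a transketolase, fell most. With quantile normalization the NRF2 list was not called (adjusted p 0.117).

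Genes of ribosome biogenesis and of the response to amino acid shortage rose as lists. Of 30 MYC target genes of ribosome biogenesis, 25 rose, 4 fell and 1 was not called by either adjustment (median 0.71, camera adjusted p 1.07e-05, adjusted p = 0.524 with an estimated correlation), led by Rrs1 (2.17) and Utp20 (1.66), both ribosome assembly factors. Of 31 genes of the ATF4 amino acid response, 21 rose, 9 fell and 1 was not called by either adjustment (median 0.68, camera adjusted p 0.0114, adjusted p = 0.524 with an estimated correlation). The transcription factor gene Atf5 rose by 3.25 on the log2 scale, the stress-induced gene Nupr1 by 2.61 and Ddit3, which encodes the transcription factor CHOP, by 2.23, from 796 ± 40.3 to 3733 ± 94.0 reads (SD, n = 4). Members of the list that went the other way include Vldlr and Cth, both chosen here after their values were seen. Vldlr fell from 791 ± 68.6 to 53.9 ± 8.50 reads and Cth from 125 ± 9.26 to 31.7 ± 8.67 reads (SD, n = 4). Asns, the asparagine synthetase gene, rose by 0.19 and was not called in the FPKM table (adjusted p 0.183). In that table it was called with the replicate block (adjusted p 0.011) and not with trends removed (0.14, adjusted p 0.148). Of 12 genes of the adenosine and cAMP response, 9 rose, 2 fell and 1 was not called by either adjustment (median 1.36, camera adjusted p 0.00505, adjusted p = 0.067 with an estimated correlation), among them the phosphatase gene Dusp4 (3.53) and Rgs1 (2.60), a regulator of G protein signalling.

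Among T cell genes the changes went both ways. Of 22 CD8 effector genes, 12 rose, 9 fell and 1 was not called by either adjustment, and the list was not called (median 0.28, camera adjusted p 0.34, adjusted p = 0.61 with an estimated correlation). Of 16 genes of the T cell receptor complex and CD8, 11 fell, or 12 adjusted over the list alone, 4 rose by either adjustment and 1 was not called over all genes, including falls of Cd3g (-1.68) and the kinase gene Zap70 (-1.31). That list (median -0.63, camera adjusted p 0.0314, adjusted p = 0.524 with an estimated correlation) was not called with quantile normalization (adjusted p 0.234) or in the FPKM table (adjusted p 0.145). Tnf, a cytokine gene, rose by 2.16, while Il2ra, the alpha chain of the IL-2 receptor, fell by 0.67 and Stat5b, a transcription factor downstream of that receptor, fell from 7749 ± 149 to 3868 ± 94.1 reads (SD, n = 4; adjusted p 2.2e-25). Stat5a fell by 0.22, a call that was lost with total-read scaling (-0.07, adjusted p 0.0729) and in the FPKM table (-0.34, adjusted p 0.0822). In the FPKM table it was called with the replicate block (adjusted p 0.00018) and not with trends removed (-0.01, adjusted p 0.894). Gzmb, the granzyme B gene, fell by 0.38, but with quantile normalization it was called higher by 0.24. Bcl2, a survival gene, was not called (-0.05, adjusted p 0.102), but it was called higher with total-read scaling (0.11, adjusted p 0.00239), with quantile normalization (0.21, adjusted p 6.38e-07) and in the FPKM table with the replicate block (0.15, adjusted p 0.0467). Dot1l, the H3K79 methyltransferase gene, rose by 0.13 (adjusted p 0.00471), with a negative value in the FPKM table (-0.08, adjusted p 0.731, or 0.298 with the replicate block).

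The largest changes among annotated called genes with a mean of at least 100 reads and no overlap between groups (the interaction, below, without the last condition) lay both in and outside these lists. The muscle protein gene Ttn rose by 7.50, the ubiquitin ligase gene Hecw2 by 5.81, the GTPase regulator gene Agap1 by 5.29, the chemokine gene Cxcl10 by 4.99, Zfp750 by 4.87 and the bicarbonate transporter gene Slc4a4 by 4.86. Ttn stood at 353 ± 23.7 reads without methionine and 1.17 ± 1.13 with it (SD, n = 4), so its fold depends on the added 1. The NMDA receptor gene Grin1 fell by 7.27, from 480 ± 29.9 to 2.33 ± 1.53 reads (SD, n = 4), and Bzrap1 (-6.16), Aldoc (-5.32), the selenium-binding protein gene Selenbp1 (-5.31) and Fads2 (-4.92) fell too. On GRCm38, Mat2a lies on chromosome 6 from 72432799 to 72439558, Slc43a2 on chromosome 11 from 75531694 to 75577575, and Ifng on chromosome 10 from 118441046 to 118445892.

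Over the 12469 genes tested, 10672 (85.6%) were called, 5397 higher and 5275 lower without methionine, and 3454 of them changed at least 2-fold. Markers of other cell types did not move one way: of 5 B cell markers 4 were higher (median 1.36), of 7 NK cell markers 2 were higher and 4 lower (median -0.48), and of 8 myeloid markers 2 were higher and 3 lower (median -0.26). None of these lists passed camera (adjusted p 0.34, 0.672 and 0.672). For 9 CD4 T cell markers, 3 higher and 3 lower, the median was -0.09 and the mean 0.22, with a positive median under total-read scaling (0.06) and camera adjusted p 0.75. Scaling to total reads moved the median log2 fold change of all genes to 0.17 in this comparison, to 0.15 for supernatant over complete fresh medium and to -0.14 for methionine addition to supernatant, so smaller changes hold relative to the scaling. From FPKM, 6786 genes were called, and 9255 with the replicate block.

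**Figure D2:**
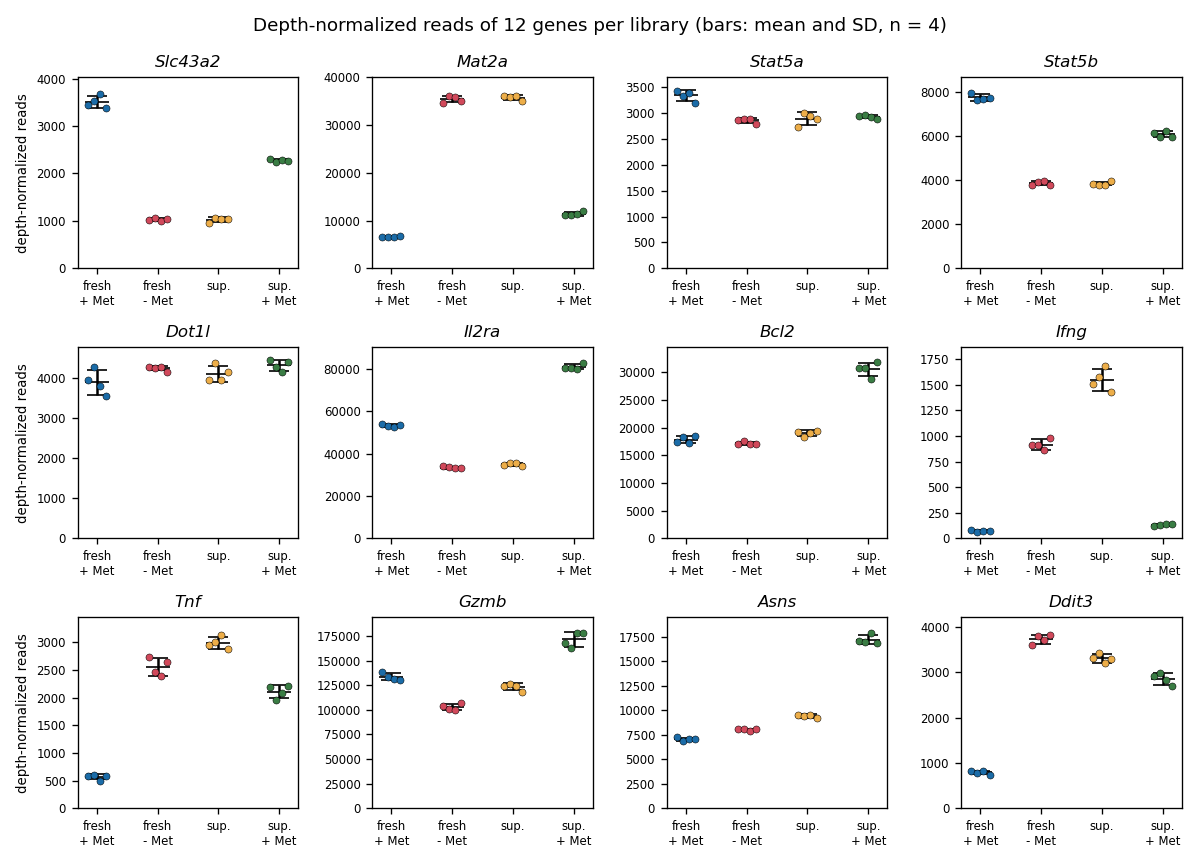
Depth-normalized reads of the 12 fixed genes, 1 point per library, with bars for the mean and SD of 4 libraries in complete fresh medium, fresh medium without methionine, supernatant and supplemented supernatant. Mat2a and Ifng are highest in the 2 media without added methionine, and Asns is highest in supplemented supernatant (17200 ± 441 reads, SD, n = 4).

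The second comparison asked how melanoma supernatant changed the cells relative to complete fresh medium. The supernatant profile resembled that of methionine removal: Mat2a rose by 2.43, Slc43a2 fell by 1.77, Ifng rose by 4.42 and Tnf by 2.39. The cytokine gene Lta, encoding lymphotoxin alpha, rose by 4.32, from 1201 ± 57.6 to 24039 ± 671 reads (SD, n = 4; adjusted p 2.74e-41). Cish, a STAT5-induced inhibitor of cytokine signalling, rose by 2.72, from 3184 ± 138 to 20943 ± 968 reads (SD, n = 4). Stat5b (-1.01) and Il2ra (-0.61) fell.

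All 21 glycolysis genes fell by both adjustments (mean -1.97, camera adjusted p 3.84e-10, adjusted p = 0.0489 with an estimated correlation), including Pgk1 (-2.96), a kinase of the pathway, and Aldoc (-4.02). All 19 hypoxia response genes fell by both adjustments (median -1.94, camera adjusted p 4.78e-08, adjusted p = 0.0489 with an estimated correlation). Of 25 cholesterol synthesis genes, 24 fell and 1 was not called by either adjustment (median -2.11, camera adjusted p 5.19e-11, adjusted p = 0.0597 with an estimated correlation), among them Hmgcs1 (-3.17), an early enzyme of the pathway, and Fdps (-3.61). Of 34 mitosis and S phase genes, 33 fell and 1 was not called by either adjustment (median -0.91, camera adjusted p 4.39e-11, adjusted p = 0.0597 with an estimated correlation). Of 25 genes of the IL-2 and STAT5 axis, 17 rose and 8 fell by both adjustments (median 0.65, camera adjusted p 0.024, adjusted p = 0.38 with an estimated correlation), and Lta and Cish, a target and an inhibitor of the pathway, rose most. Of 30 ribosome biogenesis genes, 25 rose, 3 fell, or 4 adjusted over the list alone, and 2 were not called over all genes (median 0.86, camera adjusted p 2.58e-06, adjusted p = 0.38 with an estimated correlation), including the RNA polymerase I subunit gene Polr1b (1.63).

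The genes of largest rise were Ttn (7.28), Slc4a4 (6.36), Hecw2 (6.29), Agap1 (5.39), the myosin gene Myo16 (4.84) and the scaffold gene Pdzk1 (4.74). Those of largest fall were Grin1 (-7.51), Bzrap1 (-6.65), Selenbp1 (-6.04), Fads2 (-4.85), the integrin gene Itga7 (-4.52) and Smtnl2 (-4.36). Both rankings are among genes that met the naming rule's conditions. Ddit3 rose by 2.06, Asns by 0.42 and Bcl2 by 0.09 (adjusted p 0.00604, not called in the FPKM table with adjusted p 0.253, or 0.0058 with the replicate block). Stat5a fell by 0.21, a call lost with total-read scaling (-0.06, adjusted p 0.0967), in the FPKM table (-0.26, adjusted p 0.193) and there with trends removed (0.0016, adjusted p 0.985). In the FPKM table with the replicate block Stat5a was called (adjusted p 0.0019). Gzmb fell by 0.11, a call lost with total-read scaling (0.03, adjusted p 0.35), in the FPKM table (-0.14, adjusted p 0.0891) and there with trends removed (-0.09, adjusted p 0.38). It was called higher with quantile normalization (0.50) and lower in the FPKM table with the replicate block (adjusted p 0.019). Dot1l was not called (0.08, adjusted p 0.0697; -0.067 in the FPKM table). Dot1l was called higher with total-read scaling (0.23), quantile normalization (0.10) and edgeR on 15 libraries (0.09), in the FPKM table with trends removed (0.15), and without replicate 1 of complete fresh medium (0.13, adjusted p 0.00331), replicate 0 of supernatant (0.099, adjusted p 0.0416) or replicate 2 of supernatant (0.097, adjusted p 0.0452).

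In this comparison 10664 genes were called, 5360 higher and 5304 lower, 3440 of them at least 2-fold, and 6717 in the FPKM table, or 9216 there with the replicate block. Across genes, the fold changes of methionine removal and of supernatant, both against complete fresh medium, had a Pearson r of 0.979 and a Spearman rho of 0.977. Because both share the same 4 libraries, r averaged 0.520 in simulations in which no gene changed, but the covariance there averaged 0.0084 against 1.20 observed, and with the shared libraries split r was 0.960 to 0.964. Of the genes called in both, 5054 were higher in both and 4934 lower in both, where independent calls would give 2320 and 2244.

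The third comparison asked whether methionine added to the supernatant moved expression back. It did so for most genes: of the 5360 genes that supernatant raised, 4464 (83.3%) fell when methionine was added, and of the 5304 it lowered, 4406 (83.1%) rose. With separate pairs of supernatant libraries for the 2 comparisons, so that none is shared, the shares were 81.0% to 83.3% and 80.3% to 82.3% over 6 splits. Mat2a fell by 1.64, from 35760 ± 518 to 11438 ± 370 reads (SD, n = 4), and Slc43a2 rose by 1.15, from 1030 ± 42.7 to 2280 ± 27.0 reads (SD, n = 4). Ifng fell by 3.53, from 1548 ± 108 to 133 ± 9.87 reads (SD, n = 4). Il2ra rose by 1.21, to 81063 ± 1156 reads (SD, n = 4), above its level in complete fresh medium (53416 ± 526, SD, n = 4). Of the raised genes that fell back, 1703 were then not called against complete fresh medium, 1874 were still higher and 887 were lower. Of the lowered ones, 1589 were not called, 1917 were still lower and 900 were higher. Over all 5360 raised and all 5304 lowered genes, the median share of the change that was reversed was 79.9% and 80.2%. The same supernatant libraries enter both changes in these 2 medians.

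Metabolic lists rose with methionine. Of 25 cholesterol synthesis genes, 23 rose, 1 fell and 1 was not called by either adjustment (median 1.34, camera adjusted p 4.37e-09, adjusted p = 0.103 with an estimated correlation), including Fdps (3.04). Of 21 glycolysis genes, 19 rose and 2 were not called by either adjustment (median 1.13, camera adjusted p 3.52e-08, adjusted p = 0.0788 with an estimated correlation), including Aldoc (3.31) and Pgk1 (2.45). Of 19 hypoxia response genes, 16 rose, 2 fell and 1 was not called by either adjustment (median 1.19, camera adjusted p 0.000181, adjusted p = 0.103 with an estimated correlation), including Bnip3 (2.58) and Ero1l (2.33), an oxidase of the endoplasmic reticulum. Of 44 oxidative phosphorylation genes, 41 rose and 3 were not called by either adjustment (median 0.47, camera adjusted p 1.26e-08, adjusted p = 0.278 with an estimated correlation). Of 34 mitosis and S phase genes, 30 rose, 2 fell and 2 were not called by either adjustment (median 0.69, camera adjusted p 1.13e-08, adjusted p = 0.103 with an estimated correlation), including Bub1 (1.34) and Ccnb2 (1.31). Of 18 fatty acid synthesis genes, 13 rose, 3 fell and 2 were not called by either adjustment (median 0.82, camera adjusted p 0.000264, adjusted p = 0.103 with an estimated correlation), including Fads2 (4.10) and Acsl3 (2.13), an acyl-CoA synthetase gene.

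Of 20 genes of cytosolic tRNA synthetases, 16 rose, 1 fell and 3 were not called by either adjustment (median 0.66, camera adjusted p 8.54e-05, adjusted p = 0.165 with an estimated correlation), led by Qars (1.38) and Cars (1.22), the enzymes for glutamine and cysteine. Of 20 serine and folate one-carbon genes, 14 rose, 4 fell and 2 were not called by either adjustment (median 0.66, camera adjusted p 0.00188, adjusted p = 0.209 with an estimated correlation), including the mitochondrial folate enzyme genes Aldh1l2 (3.30) and Mthfd1l (1.49). Of 31 ATF4 response genes, 20 rose, 8 fell and 3 were not called by either adjustment (median 0.49, camera adjusted p 0.0137, adjusted p = 0.391 with an estimated correlation), and with quantile normalization this list was not called (adjusted p 0.0857). Within it, Cth, which makes cysteine by transsulfuration, rose by 4.89, from 54.2 ± 4.02 to 1637 ± 85.0 reads (SD, n = 4), and the lipoprotein receptor gene Vldlr rose by 3.57. Of 24 NRF2 and glutathione genes, 19 rose, 4 fell and 1 was not called by either adjustment (median 0.70, camera adjusted p 0.00129, adjusted p = 0.278 with an estimated correlation), including Nqo1 (3.67) and the cystine transporter gene Slc7a11 (1.91).

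Lists of signalling and T cell genes moved both ways. All 12 adenosine and cAMP response genes fell by both adjustments (median -1.72, camera adjusted p 2.79e-06), with Rgs1 (-3.36) and Rgs2 (-3.12), regulators of G protein signalling, the most changed, and adjusted p = 0.0151 with an estimated correlation. Of 22 CD8 effector genes, 16 fell, 4 rose and 2 were not called by either adjustment (median -0.56, camera adjusted p 0.0166, adjusted p = 0.209 with an estimated correlation); those that fell include Ifng and the chemokine gene Ccl3 (-3.41). Of 20 genes of inhibitory receptors and exhaustion, 14 fell, 4 rose and 2 were not called by either adjustment (median -0.75, camera adjusted p 0.0136, adjusted p = 0.103 with an estimated correlation), including the nuclear receptor gene Nr4a3 (-2.23) and the inhibitory receptor gene Btla (-2.14). Of 30 genes of the type I interferon response, 21 fell, 6 rose and 3 were not called by either adjustment (median -0.58, camera adjusted p 0.0102, adjusted p = 0.165 with an estimated correlation), including the antiviral gene Ifit1 (-2.80) and Mx2 (-4.26), which the annotation lists as a polymorphic pseudogene and which had as few as 1 read in a library. Of 16 T cell receptor complex and CD8 genes, 10 rose, 3 fell and 3 were not called by either adjustment (median 0.38, camera adjusted p 0.0166, adjusted p = 0.346 with an estimated correlation), including Cd3g (1.33) and the kinase gene Lck (1.10). With quantile normalization that list was not called (adjusted p 0.303), nor in the FPKM table (adjusted p 0.105).

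Other large rises were those of Grin1 (6.48), Bzrap1 (5.87), Selenbp1 (4.28) and Cyp11a1 (3.65), the side-chain cleavage enzyme of steroid synthesis. Ttn (-6.65), Hecw2 (-6.45), Plaur (-5.79), the urokinase receptor gene, Pdzk1 (-5.21), Cxcl10 (-5.18) and the lens filament gene Bfsp2 (-5.04) fell most. That ranking is among genes that met the naming rule's conditions. Bcl2 rose by 0.68, Stat5b by 0.66, Gzmb by 0.48 and Asns by 0.87, while Tnf (-0.51) and Ddit3 (-0.21) fell, the latter not called in the FPKM table (-0.14, adjusted p 0.622, or 0.0549 with the replicate block), nor there with trends removed (adjusted p 0.547). Stat5a (0.02, adjusted p 0.6) and Dot1l (0.07, adjusted p 0.101) were not called, but Stat5a was called lower with total-read scaling (-0.11) and in the FPKM table with trends removed (-0.18). Dot1l was called higher with library weights (0.099, adjusted p 0.012), in the FPKM table with the replicate block (0.20, adjusted p 0.0174) and without replicate 1 of supernatant (0.10, adjusted p 0.0243).

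In all, 10433 genes were called, 5218 higher and 5215 lower with methionine, 2785 of them at least 2-fold, and 6027 in the FPKM table, or 8859 there with the replicate block. The effect of no added methionine in fresh medium and in supernatant, 2 comparisons with no shared library, had a Pearson r of 0.895 and a Spearman rho of 0.879 across genes, with the same sign in 85.8% of genes. Of genes called in both, 4462 were higher and 4384 lower without added methionine in both media, where independent calls would give 2257 and 2208. The change by methionine addition and the change by supernatant had r of -0.897, against a mean of -0.503 in simulations in which no gene changed and -0.883 to -0.877 with the shared libraries split.

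**Figure D3:**
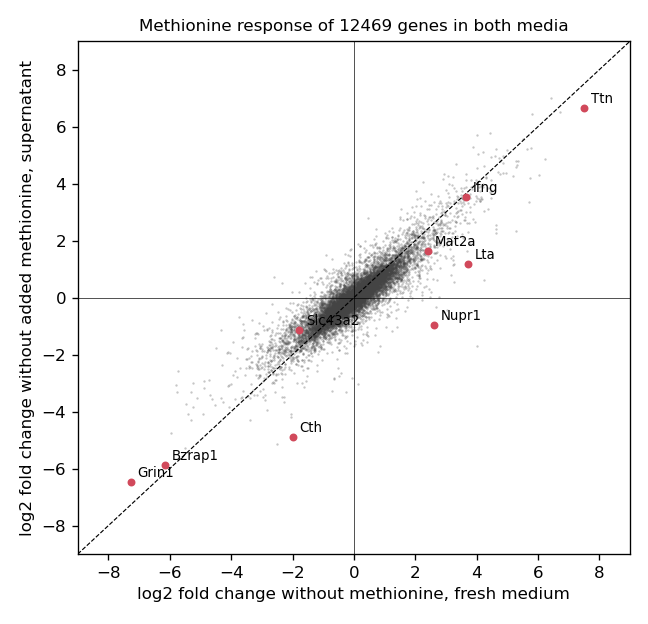
Log2 fold change of 12469 genes without methionine in fresh medium (horizontal axis) and without added methionine in supernatant (vertical axis), 1 point per gene, with 9 genes named and the line of equal change dashed. Points follow the line (r 0.895), while Nupr1 and Cth lie away from it.

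**Figure D4:**
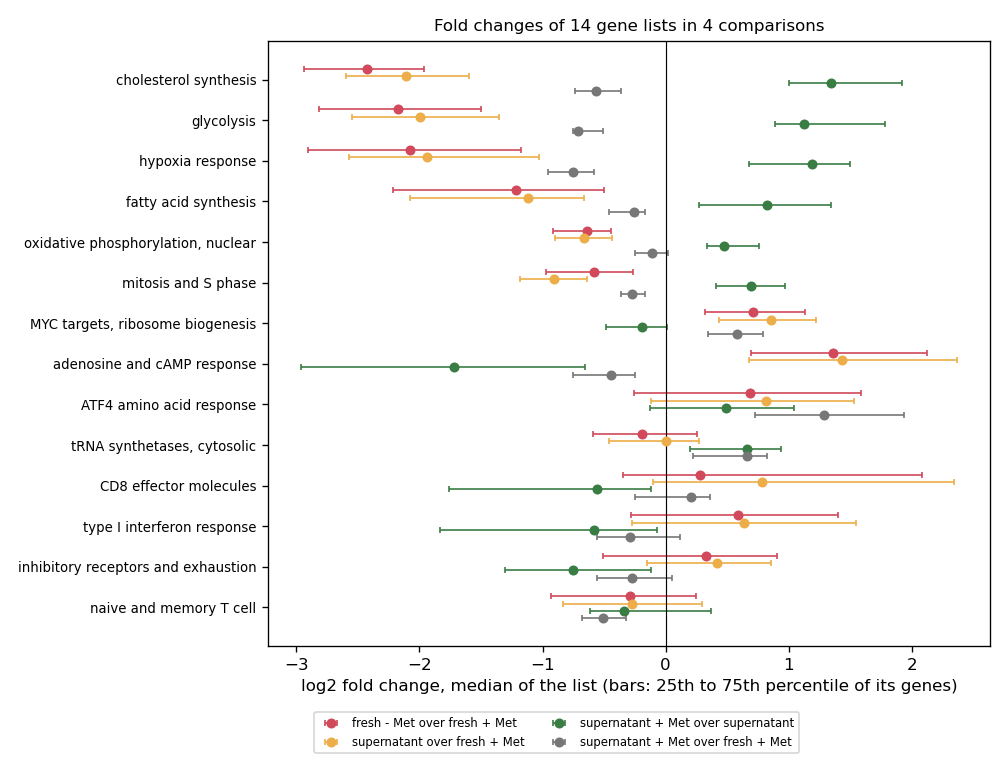
Median log2 fold change of 14 gene lists in 4 comparisons, with bars from the 25th to the 75th percentile of each list's genes. Cholesterol synthesis stands at -2.42 for methionine removal, -2.11 for supernatant, 1.34 for methionine addition and -0.57 for supplemented supernatant over complete fresh medium.

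The fourth comparison asked what still differed between supernatant and fresh medium when both contained added methionine. Genes of the amino acid response were higher in supplemented supernatant, and glycolysis, sterol and naive or memory T cell genes were lower. Of 31 ATF4 response genes, 29 rose and 2 fell by both adjustments, with a median of 1.29, and the cysteine-making enzyme gene Cth was higher by 3.70, at 1637 ± 85.0 against 125 ± 9.26 reads (SD, n = 4). The list passed camera (adjusted p 3.74e-21) and had adjusted p = 0.0105 with an estimated correlation. Cox6a2, a muscle-type subunit of cytochrome c oxidase, rose by 5.71, from 7.65 ± 3.76 to 413 ± 39.8 reads (SD, n = 4), and Aldh1l2 rose by 3.65.

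Of 20 tRNA synthetase genes, 17 rose, 2 fell and 1 was not called by either adjustment (median 0.66, camera adjusted p 3.39e-10, adjusted p = 0.0254 with an estimated correlation). Of 16 genes of the methionine cycle and salvage, 13 rose, 0 fell and 3 were not called by either adjustment (median 0.36, camera adjusted p 3.78e-05, adjusted p = 0.0185 with an estimated correlation). Of 12 neutral amino acid transporter genes, 8 rose, 3 fell and 1 was not called by either adjustment (median 0.54, camera adjusted p 0.00349, adjusted p = 0.038 with an estimated correlation). Of 30 ribosome biogenesis genes, 28 rose, 1 fell, or 2 adjusted over the list alone, and 1 was not called over all genes (median 0.58, camera adjusted p 1.29e-13, adjusted p = 0.0729 with an estimated correlation). Of 25 IL-2 and STAT5 axis genes, 14 rose, 6 fell and 5 were not called by either adjustment (median 0.60, camera adjusted p 4.55e-05, adjusted p = 0.0355 with an estimated correlation).

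Of 20 naive and memory T cell genes, 17 fell, 2 rose and 1 was not called by either adjustment (median -0.51, camera adjusted p 2.66e-07, adjusted p = 0.0105 with an estimated correlation). Of 21 glycolysis genes, 20 fell and 1 rose by both adjustments (median -0.71, camera adjusted p 5.89e-11, adjusted p = 0.0136 with an estimated correlation), and of 25 cholesterol synthesis genes, 24 fell and 1 was not called by either adjustment (median -0.57, camera adjusted p 4.14e-11, adjusted p = 0.0355 with an estimated correlation). Of 20 inhibitory receptor and exhaustion genes, 13 fell, 3 rose, or 4 adjusted over the list alone, and 4 were not called over all genes (median -0.27, camera adjusted p 0.0105, adjusted p = 0.0453 with an estimated correlation), and this list was not called in the FPKM table (adjusted p 0.0704). Itga7 (-2.75), the cytochrome gene Cyp2s1 (-2.02) and the guanylate cyclase gene Gucy2e (-1.99) fell most among genes that met the naming rule's conditions. Of 5 melanoma markers tested, 1 rose, 1 fell and 3 were not called (median -0.06, and 0.07 with quantile normalization), with camera adjusted p 0.625.

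Here 8106 genes were called, 4049 higher and 4057 lower, and 604 of them differed at least 2-fold. From FPKM, 1958 genes were called, and 5759 with the replicate block.

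The fifth comparison set supernatant against fresh medium without methionine, to ask how the 2 media without added methionine differed. The methionine left in the supernatant is not given. Differences were small, with a median absolute log2 fold change of 0.09 over all genes. All 34 mitosis and S phase genes were lower in supernatant, by both adjustments, with a median of -0.32 (camera adjusted p 1.37e-40, adjusted p = 0.002 with an estimated correlation). The adhesion gene Cdh1 rose by 1.67 and Oplah, an enzyme of the glutathione cycle, by 1.66.

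Of 25 cholesterol synthesis genes, 18 rose, or 19 adjusted over the list alone, 0 fell and 7 were not called over all genes (median 0.38, camera adjusted p 7.91e-19, adjusted p = 0.0103 with an estimated correlation). Of 21 glycolysis genes, 17 rose, or 18 adjusted over the list alone, 0 fell and 4 were not called over all genes (median 0.25, camera adjusted p 1.88e-15, adjusted p = 0.00433 with an estimated correlation). Of 22 CD8 effector genes, 15 rose, or 16 adjusted over the list alone, 1 fell by either adjustment and 6 were not called over all genes (median 0.34, camera adjusted p 4.36e-10, adjusted p = 0.00433 with an estimated correlation). Of 20 inhibitory receptor and exhaustion genes, 12 rose, or 13 adjusted over the list alone, 2 fell by either adjustment and 6 were not called over all genes (median 0.20, camera adjusted p 0.000107, adjusted p = 0.00986 with an estimated correlation). Of 7 NK cell markers, which include Gzma and Eomes that CD8 T cells also express, 5 rose and 2 were not called by either adjustment (median 0.57, camera adjusted p 4.82e-06, adjusted p = 0.0106 with an estimated correlation). Of 9 CD4 T cell markers, 2 rose and 7 were not called by either adjustment (median 0.21, camera adjusted p 0.0385, adjusted p = 0.0909 with an estimated correlation). Of 16 T cell receptor complex and CD8 genes, 9 rose, or 10 adjusted over the list alone, 0 fell and 7 were not called over all genes (median 0.11, camera adjusted p 1.74e-06, adjusted p = 0.0602 with an estimated correlation). Zfp750 (-0.80), the cell cycle repressor gene E2f7 (-0.78) and the tumour suppressor gene Hic1 (-0.78) fell most. That ranking is among annotated called genes with a mean of at least 100 and no overlap between groups. In the FPKM table Zfp750 (-0.78, adjusted p 0.0799) and Hic1 (-0.64, adjusted p 0.818) were not called. Both were called there with the replicate block (adjusted p 0.0030 and 0.0064).

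In this comparison 3344 genes were called, 1740 higher and 1604 lower in supernatant, and 48 of them differed at least 2-fold. From FPKM, 32 genes were called, and 1441 with the replicate block.

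The last comparison tested whether the effect of methionine differed between supernatant and fresh medium. Positive values mean that expression rose more, or fell less, with methionine in supernatant than in fresh medium. Negative values mean that it rose less, or fell more. Cox6a2 had the highest value (5.70) among annotated called genes with a mean of at least 100. Methionine changed it from 128 ± 23.5 to 413 ± 39.8 reads in supernatant and from 128 ± 25.9 to 7.65 ± 3.76 reads in fresh medium (SD, n = 4). Nupr1 (3.58) rose with methionine in supernatant, from 534 ± 35.9 to 1049 ± 24.8 reads, and was at 560 ± 34.0 without and 91.1 ± 7.40 with methionine in fresh medium (SD, n = 4). Angptl6, which encodes an angiopoietin-like secreted protein, had a value of 3.46. Values at the other end include those of Itga7 (-2.74) and Slc16a3 (-2.26).

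By this test, 28 of 31 ATF4 response genes had a more positive and 2 a more negative methionine effect in supernatant, or 3 adjusted over the list alone (median 1.05, camera adjusted p 1.12e-21, adjusted p = 0.00459 with an estimated correlation). All 25 cholesterol synthesis genes had a more negative effect, by both adjustments (median -0.90, camera adjusted p 2.18e-20, adjusted p = 0.00634 with an estimated correlation). The same held for 19 of 21 glycolysis genes, with 1 more positive, by both adjustments (median -0.95, camera adjusted p 6.73e-18, adjusted p = 0.00341 with an estimated correlation), for 18 of 19 hypoxia response genes, or 19 adjusted over the list alone (median -0.91, camera adjusted p 3.95e-16, adjusted p = 0.00341 with an estimated correlation), and for 17 of 20 naive and memory T cell genes, with 2 more positive, by both adjustments (median -0.52, camera adjusted p 7.07e-09, adjusted p = 0.00379 with an estimated correlation). Of 20 inhibitory receptor and exhaustion genes, 14 had a more negative effect, or 15 adjusted over the list alone, and 1 a more positive one by either adjustment (median -0.43, camera adjusted p 2.42e-05, adjusted p = 0.00459 with an estimated correlation).

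The methionine effect differed for 6557 genes, 3438 with a more positive and 3119 with a more negative effect in supernatant. For 601 the difference was at least 2-fold, more positive for 248 and more negative for 353. From FPKM, 750 genes were called, and 3942 with the replicate block.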

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

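Chosen only after their results were seen were the tests of library scaling in all 3 patterns, of melanoma RNA, of a lower share of CD8 T cells and of the interaction within methionine status, and the choice of 8 cytokine and chemokine genes; the removal of GC content and length trends and the splits of the libraries were chosen before.

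Most tested genes changed when methionine was left out of fresh medium (10672 of 12469). Scaling the libraries to total reads, which moved the median of all genes to 0.17, left 91.5% of the called genes with the same call and direction, so the choice between these scalings cannot be the whole cause. Both bring the libraries to a common level, so a change in total RNA per cell was not examined. Removing each library's trend on GC content and transcript length, for the 98.7% of tested genes with both values, left 93.8%. The same direction appeared in supernatant, which shares no library with this comparison (r 0.895). A response to methionine itself stays open, as does any other difference that went with methionine in both media. Of the 35 splits of the 8 libraries, 1 gave as many genes, the real one, and no other gave more than 0. In the other splits the real difference lay in the residual and held their counts down. A share of 1 in 35 is also the smallest possible, so the splits alone do not exclude chance. Whether the cultures differed in other ways was not tested.

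Genes of the amino acid response were higher in supplemented supernatant than in complete fresh medium (median 1.29). Melanoma RNA carried over with the supernatant would bring its most abundant transcripts. But Tyrp1 (0.5 reads), Dct (1 read) and Mlana (0 reads) were near 0 in supplemented supernatant, while Pmel had 29.2 reads there and 28.0 in complete fresh medium. The median of the 5 tested melanoma markers was -0.060 (0.07 with quantile normalization). All 5 had reads in complete fresh medium (from 11.25 for Trpm1 to 386.5 for Gpnmb), so that median says little about carried-over RNA. Among other scalings the lowest median of the list was 1.23 (quantile normalization), so the choice among these scalings does not explain the rise. No group isolates another nutrient or a secreted factor, so no biological explanation was tested.

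Some cytokine transcripts were higher without methionine in fresh medium: of 8 tested genes of secreted factors picked from the CD8 effector list, 7 rose (Ifng, Tnf, Ccl3, Ccl4, Xcl1, Lta and Csf2) and Ccl5 fell (-0.27), while the whole list of 22 genes, with 12 higher and 9 lower, was not called (camera adjusted p 0.34). Under every other scaling of the depth-normalized table, 7 of the 7 genes were still called higher, so the choice among these scalings does not explain their rise. These scalings all bring the libraries to a common level, so they cannot show a change in total RNA per cell. A lower share of CD8 T cells would raise the markers of whichever cell types took their place, not necessarily of all. The medians of the 4 marker lists ran from -0.48 (NK cells) to 1.36 (B cells). None of these lists was called by camera, and 3 of them had members on both sides. With fry, which asks whether a list moves at all, all 4 were called, as was nearly every list in this comparison. The adjusted p from fry was 1.21e-08 for B cells, 9.64e-07 for NK cells, 0.00022 for myeloid cells and 2.86e-07 for CD4 T cells. The NK list holds Gzma and Eomes, which CD8 T cells also express. The list of the T cell receptor complex and CD8, of which 11 genes fell and 4 rose, would be lower with a lower share (median -0.63), but its call was lost with an estimated correlation (adjusted p 0.524), with quantile normalization (0.234) and in the FPKM table (0.145). A lower share and a response to methionine cannot be told apart here.

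For supernatant against complete fresh medium (10664 genes) and for methionine added to supernatant (10433 genes), 1 of the 35 splits of the 8 libraries gave as many genes, the real one, and the highest other gave 0. For supplemented supernatant against complete fresh medium (8106 genes) and for supernatant against methionine-free fresh medium (3344 genes), 1 of 35 did and the highest other gave 1. Here too the real difference lay in the residual of the other splits and held their counts down. With 1 in 35 the smallest share possible, the splits alone do not exclude chance for these 4 comparisons. For the interaction (6557 genes), 4 of 100 regroupings gave as many, the real one included, and the highest other gave 8612. The 3 others each put 7 of the 8 libraries of one methionine status on one side of the contrast, so they measured the methionine effect; with 6 on a side, 13 regroupings gave up to 3875, and the 25 with 4 and the 58 with 5 gave 0, where the methionine effect lay in the residual. With the effects of methionine and medium removed, 1 of 100 regroupings within the same methionine status gave as many genes, the real one. The highest other gave 0. The interaction itself was not removed and lay in the residual of the other regroupings, so their counts cannot exclude chance.

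By the interaction test, the methionine effect differed between supernatant and fresh medium for 6557 genes (52.6% of those tested). It differed for 27 of the 34 named genes examined. Of these, Cox6a2, Nupr1, Angptl6, Itga7 and Slc16a3 were named for their rank among genes called in this same test, so their result was fixed by that choice. The difference was positive (log2) for Cox6a2 (5.70), Nupr1 (3.58), Angptl6 (3.46), Ddit3 (2.02), Tnf (1.66), Nqo1 (1.39), Asns (1.05), Mat2a (0.77), Bcl2 (0.63), Il2ra (0.54) and Dot1l (0.20). It was negative for Itga7 (-2.74), Slc16a3 (-2.26), Aldoc (-2.01), Bnip3 (-1.28), Selenbp1 (-1.03), Fdps (-0.97), Fads2 (-0.83), Rgs1 (-0.76), Hecw2 (-0.63), Slc43a2 (-0.63), Cd3g (-0.35), Stat5b (-0.34), Bzrap1 (-0.28), Atp5c1 (-0.27), Stat5a (-0.21) and Bub1 (-0.16).

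Single libraries stood far from the other 3 of their group, by the ratio of their gap to the range, in 11 of 312 sets of 4 values, where chance gives about 15.6. In supernatant these were, in depth-normalized reads, Slc43a2 at 966 in replicate 0 (others 1048 to 1057), Slc4a4 at 508 in replicate 1 (593 to 602), Ero1l at 8285 in replicate 1 (8924 to 8985), Mx2 at 58.6 in replicate 1 (71.5 to 72.4), Polr1b at 4648 in replicate 3 (4928 to 4968) and Btla at 1805 in replicate 3 (1850 to 1858). In supplemented supernatant they were Btla at 382 in replicate 0 (427 to 430), Slc7a11 at 591 in replicate 0 (681 to 698), Asns at 17856 in replicate 2 (16911 to 17050) and Cdh1 at 304 in replicate 2 (369 to 382). In complete fresh medium Atf5 stood at 257 in replicate 3 (274 to 275).

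Of 5971 genes that only the FPKM table lists, 130 had a mean FPKM of at least 0.5; they have no depth-normalized value and entered no comparison.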

How the results depend on the processing

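Chosen only after the data were seen were scaling to total reads, edgeR on 15 libraries, other scalings for the list tests, and the FPKM table with the replicate block or with GC content and length trends removed. The counts below follow the order methionine removal, supernatant, methionine addition, supplemented supernatant against complete fresh medium, supernatant against methionine-free fresh medium, and interaction.

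Leaving out 1 library gave 10502 to 10568, 10513 to 10590, 10236 to 10328, 7752 to 7909, 2867 to 3190 and 6257 to 6500 genes. Correlations then ranged from 0.977 to 0.980 (methionine removal with supernatant), 0.892 to 0.896 (no added methionine in both media) and -0.898 to -0.896 (methionine addition with supernatant). Total-read scaling gave 10738, 10675, 10519, 8120, 3382 and 6629 genes, edgeR 10700, 10685, 10463, 8149, 3497 and 6595, DESeq2 10657, 10641, 10421, 8113, 3522 and 6601, and the replicate block 10655, 10654, 10416, 8061, 3291 and 6521. Median-ratio factors moved nothing, since the deposited values already hold them, so they test nothing. The 4690 genes with a mean below 10 were not tested, and the effect of sequencing depth was not examined.

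A 2-fold minimum left 3454, 3440, 2785, 604, 48 and 601 genes, by its construction. The FPKM table gave 6786, 6717, 6027, 1958, 32 and 750. Over 11221 genes tested in both tables, fold changes of methionine removal had r of 0.982, but the median standard error was 3.66 times larger in FPKM (0.172 against 0.0471). The ratio of FPKM to depth-normalized value followed GC content across 10683 genes, with rho of 0.47 to 0.88 in replicates 0 and 2 and -0.88 to -0.64 in replicates 1 and 3 of every group. With the GC content and length trends removed, the FPKM table gave 8454, 8425, 8028, 4529, 636 and 2736 genes, and with the replicate block 9255, 9216, 8859, 5759, 1441 and 3942, so part of the lower counts goes with trends shared by libraries of the same number. The correlations were 0.812, 0.930 and -0.863 in the FPKM table and 0.904, 0.984 and -0.902 with a mean of at least 50, in the order no added methionine in both media, methionine removal with supernatant, and methionine addition with supernatant; the cause was not tested.

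Gene lists called numbered 11, 10, 15, 18, 18 and 19. With an estimated correlation they were 2, 2, 1, 12, 10 and 14, since lists of co-varying genes then get a wider error. With fry, which asks whether a list moves at all, they were 35, 32, 35, 36, 23 and 30. Over all lists and alternatives, 1323 results kept their side of the threshold, 115 gained a call and 62 lost it, and 0 lists called both ways changed direction. The median of a list changed sign in 48 of 1284 comparisons with another scaling, table or test, 0 of them for a list called by camera.

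Among named genes, 4187 results were kept, 10 gained a call, 34 lost it and 11 reversed. Of the 34 losses, 19 came with the 2-fold minimum, by its construction. The cause of the other changes was not tested. Methionine removal gave Bcl2 at 0.11 with total-read scaling, 0.21 with quantile normalization and 0.15 in the FPKM table with the replicate block, against -0.05. It gave Dot1l at -0.081 in the FPKM table, with and without that block, and Gzmb at 0.24 with quantile normalization. Supernatant gave Gzmb at 0.032 with total-read scaling and 0.50 with quantile normalization, and Stat5a at 0.0016 in the FPKM table with trends removed. Methionine addition gave Stat5a at -0.11 with total-read scaling and -0.18 in the FPKM table with trends removed.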

Other observations

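The single genes named here were chosen after their values were seen. Of 25 genes of the pro-death list, 15 rose and 7 fell when methionine was removed from fresh medium, and the list was not called (median 0.28, camera adjusted p 0.0975, adjusted p = 0.524 with an estimated correlation). Its highest members were Aen (2.85), Tnfrsf10b (2.05), Fadd (1.99), Mdm2 (1.73) and Cdkn1a (1.68). Casp9 (-1.64), Casp6 (-1.49) and Bmf (-1.42) were lowest.

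Eef1a1, an elongation factor, took 0.71% ± 0.0089 of reads in fresh medium without methionine and 1.45% ± 0.036 in complete fresh medium, and 0.81% ± 0.0034 in supernatant and 1.72% ± 0.032 in supplemented supernatant (SD, n = 4).

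Of 23 tested genes of histone lysine methyltransferases, 13 rose and 9 fell with methionine removal and 1 was not called by either adjustment (median 0.17, camera adjusted p 0.558, adjusted p = 0.714 with an estimated correlation). Polyamine synthesis genes were split evenly, with 5 higher and 5 lower of 11 (camera adjusted p 0.785), and their median (-0.06, but 0.10 with total-read scaling and 0.26 in the FPKM table) and mean (0.14) differed in sign.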
